A study of Mus musculus with 4 samples.

How the data were processed

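Sciatic nerves of 4-month-old mice of 4 genotypes (WT, PKO, NF1 and PKO-NF1) were profiled by RNA sequencing, with 1 library per genotype. Per the labels' protocols, nerves were flash frozen, RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with a TruSeq RNA kit. The labels give neither the number of animals in a library nor their sex. The NF1 library is labelled a repeat at 4 months. The authors deposited 1 table of whole-number counts for 24062 gene symbols. The submitters' processing notes name FastQC 0.11.7, HISAT2 2.0.5, featureCounts 1.5.2 and the mouse build mm10. Strandedness, annotation, read length and the handling of reads that map to several places are not given in the sources used here. Counts of overlapping genes (such as Nf1 with Omg, or P2ry14 with Med12l), of antisense genes and of near-identical copies (such as the ribosomal protein genes and their pseudogenes) are therefore uncertain. The table was used as deposited, without conversion of unit, and no column of it was left out. Mitochondrially encoded transcripts were not analysed here.

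Library depth was 14111201, 20362685, 19064779 and 17771101 counts in WT, PKO, NF1 and PKO-NF1, in that order. Counts were scaled to CPM with edgeR 4.0.16 TMM factors (1.20, 0.873, 1.03 and 0.922), and 3 counts, the limit that a count of 0 allows, came to 0.177, 0.169, 0.152 and 0.183 CPM. Genes at 1 CPM or more in at least 1 library were kept, 14700 in all. The 5 comparisons were made as ratios of TMM-scaled CPM: NF1 vs WT, PKO-NF1 vs PKO, PKO vs WT, PKO-NF1 vs NF1 and PKO-NF1 vs WT. Each ratio has an exact conditional (Clopper-Pearson) 95% interval, which covers counting error only; PCR reads without molecular identifiers are not independent molecules. A gene counted as higher or lower when it was at least 2-fold apart and its interval excluded 1. Where 1 library had 0 counts the fold was taken against the limit of 3 counts in that library and is given as at least that size. Overlaps of calls are set beside the product of both list sizes divided by the number of genes. The genes that return in PKO-NF1 are set beside 100 simulations with negative binomial counts and no P2ry14 effect.

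The model over all 4 libraries was additive: edgeR glmQLFit and glmQLFTest with a term for Nf1 status and a term for P2ry14 status, genes at 1 CPM in at least 2 libraries (14105 genes), and Benjamini-Hochberg adjusted p under 0.05. Its 1 residual degree of freedom is the interaction, so a true interaction enters as error. With 1 library per genotype, p-values set a term against that departure from additivity, and not against a spread between animals. Labels do not say which animals were separate. The common biological coefficient of variation was 0.27.

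In total 39 gene lists with 924 entries were fixed before the data were examined, covering the blood-nerve barrier and vessel wall, Schwann cell states, immune cells, signalling and stress, and other tissue or RNA quality; 15 entries were found under another symbol and 20 were not found, and the list of mitochondrially encoded genes could not be used. For each list and comparison the median log2 ratio over measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. For the additive model, calls are given adjusted over all genes and adjusted over the list alone. Transcript length, GC content and coordinates came from GENCODE M21 on GRCm38, to which 22750 symbols matched directly and 934 through a RefSeq synonym, 98.4% in all; 378 did not match.

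The genes named were chosen by a rule fixed at the same time. They are Nf1 and P2ry14; the 12 highest and 12 lowest genes of each pairwise comparison other than PKO-NF1 vs WT, by the interval bound nearest to no change, among genes at 5 CPM or more in either library and outside predicted, ribosomal, mitochondrial and other-tissue genes; the 12 in each direction over both Nf1 pairs and over both P2ry14 pairs; for each list up to 4 members in each direction and the 4 most abundant; and the 10 smallest adjusted p per term of the additive model. Genes named from outside this rule are said to be so. Results for some genes that the rule selects are not reported here.

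Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, total counts only, no expression filter, a 5 CPM filter, a 1.5-fold threshold, removal of other-tissue lists with scaling recomputed, removal of list members shared between lists, and, for the additive model, the DESeq2 Wald test, models with 1 genotype term, and leaving out each library. One alternative was added after trends over transcript length and GC content had been seen: splines with 4 degrees of freedom in log10 longest-transcript length and in GC content were fitted per comparison on genes outside the other-tissue lists and subtracted. The subtracted trend of the pairwise ratios was then centred so that the median gene kept its value, a step added after an uncentred version had been seen; the offsets of the additive model were left uncentred.

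The ratio step was tested on simulated Poisson counts for NF1 vs WT with 14700 genes, which vary by counting error alone. Of the intervals 95.6% held the true ratio. The rule was met by 100% of 100 genes simulated at 4-fold, 46% of 100 simulated at 2-fold and 38 of 14500 unchanged genes. These shares leave out variation between animals and libraries, so they are not error rates of the calls below. Of simulated lists of 20 genes with no shift 6.5% lay outside the 2.5th to 97.5th percentile, and of those shifted by 0.5 log2 58% did. In that simulation genes varied independently. Members of a real list can vary together, so the percentiles describe these libraries and are not error rates. The additive model was tested on simulated counts for the Nf1 term with 14105 genes and recovered 12% of 100 genes at 2-fold and 93% of 100 genes at 4-fold, with 1 false call. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, patsy 1.0.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.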

Results

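Gene expression was measured in sciatic nerve of 4-month-old mice of 4 genotypes, with 1 RNA sequencing library for each genotype. WT nerves carried neither mutation. PKO nerves lacked P2ry14, which encodes a G protein-coupled receptor for UDP-sugars. NF1 nerves carried floxed alleles of Nf1, which encodes the RAS GTPase-activating protein neurofibromin, together with Dhh-Cre, a Cre driver active in the Schwann cell lineage. PKO-NF1 nerves carried both mutations. The series asks how genes of the blood-nerve barrier, the endothelial and perineurial seal of the nerve, are expressed in Nf1-deficient mice. Total counts were 14111201 in WT, 20362685 in PKO, 19064779 in NF1 and 17771101 in PKO-NF1, and 3 counts corresponded to between 0.152 and 0.183 CPM (counts scaled to library size). With 1 library per genotype there were no replicates and no replicate check on any difference. Each ratio below therefore compares 2 libraries, and its 95% interval covers counting error only.

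P2ry14 was lower in both P2ry14-null libraries, at 10.9 CPM in PKO against 37.6 CPM in WT (3.47-fold lower, interval 2.95 to 4.10) and 10.6 CPM in PKO-NF1 against 65.3 CPM in NF1 (6.18-fold lower, 5.27 to 7.29). The gene P2ry14 (ENSMUSG00000036381) overlaps Med12l on chromosome 3, from 59113855 to 59153618 on the minus strand of GRCm38. P2ry14 was 1.73-fold higher in NF1 than in WT (1.58 to 1.91). Its counts were still 193 in PKO and 173 in PKO-NF1, and the table holds gene totals, not exons. Nf1 (ENSMUSG00000020716; chromosome 11, 79339693 to 79581612, plus strand), which overlaps Evi2, Evi2a, Evi2b and Omg, was at 72.8 CPM in WT, 63.4 CPM in NF1, 41.0 CPM in PKO and 20.5 CPM in PKO-NF1. Nf1 was 1.15-fold lower in NF1 than in WT (1.06 to 1.24) and 2.0-fold lower in PKO-NF1 than in PKO (1.75 to 2.28), so gene-level counts set the NF1 library little apart from WT. Nf1 was also lower in PKO, whose genotype leaves it intact, than in NF1. With the trends over transcript length and GC content removed, the NF1 vs WT log2 ratio of Nf1 was -0.02, and that of PKO-NF1 vs PKO was -0.58.

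**Figure D1:**
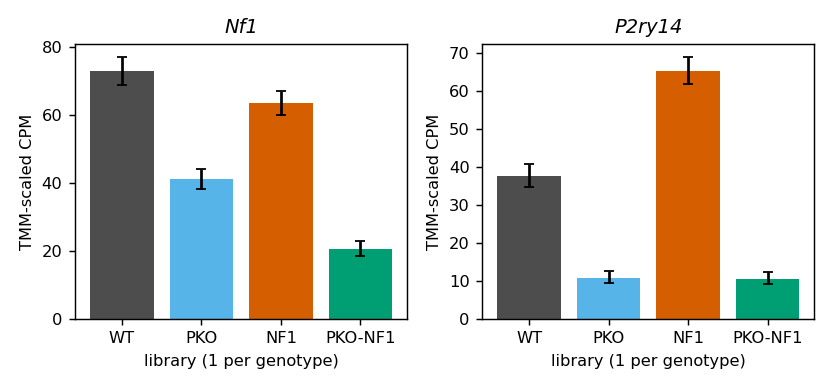
TMM-scaled CPM of Nf1 (left) and P2ry14 (right) in each library; bars start at 0 and error bars are exact Poisson 95% intervals, which cover counting error only. P2ry14 was at 10.9 CPM in PKO and 10.6 CPM in PKO-NF1, and Nf1 was lowest in PKO-NF1 at 20.5 CPM.

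The libraries differed in transcripts of other tissue and in sex-linked transcripts. Skeletal muscle genes took 8.80% of counts in NF1 against 0.220% in WT, 0.0552% in PKO and 0.0838% in PKO-NF1. Ribosomal protein genes took 2.87% of counts in WT, 10.6% in PKO, 8.50% in PKO-NF1 and 5.23% in NF1. Xist, which is transcribed from the inactive X chromosome, had 10304 counts in WT, 4948 in PKO, 39699 in NF1 and 9 in PKO-NF1. The Y-linked gene Ddx3y had 813 counts in WT, 396 in PKO, 842 in PKO-NF1 and none in NF1, and Eif2s3y had 566, 419, 1190 and 0 in the same order. The NF1 library is labelled a repeat; whether it was made in another batch is not given in the sources used here, and if it was, batch and genotype cannot be told apart in comparisons that contain it. WT and PKO held RNA of both sexes, NF1 only that of females by these genes, and PKO-NF1 Y-linked counts with almost no Xist. Across genes the Spearman correlation of expression was 0.952 between PKO and PKO-NF1 and 0.95 between WT and PKO, and NF1 correlated with the other libraries at 0.896 to 0.917; genes are not independent replicates.

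The comparison of NF1 with WT asks what differs in nerve when Nf1 is lost in the Dhh-Cre lineage. Endothelial cell genes were lower in NF1: 12 of 22 measured members were at least 2-fold lower and none higher, and the median log2 ratio was -1.13. Examples were Vwf, the carrier of coagulation factor VIII (152 to 29.2 CPM; 5.20-fold lower, 4.75 to 5.70), the endothelial receptor kinase Tie1 (3.76-fold lower, 3.28 to 4.31) and Mmrn2 (4.14-fold lower, 3.49 to 4.93). Myelin genes were also lower, with 13 of 19 at least 2-fold lower and a median of -1.19; Mbp was 3.02-fold lower (2.99 to 3.05). Skeletal muscle genes were higher, 68 of 70 by at least 2-fold with a median of 48.7-fold.

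Genes of the barrier were on the lower side in NF1, with list medians less negative than the -1.13 of the endothelial list. Of the 22 endothelial genes 9 are also in another list. A change of barrier genes was therefore not separated from less endothelial RNA in the NF1 library. Of 25 tight junction genes 5 were lower and none higher (median -0.46). Cldn5, the main claudin of endothelial tight junctions, was 2.16-fold lower (1.98 to 2.37), the endothelial adhesion molecule Esam 2.23-fold lower (1.97 to 2.52) and Cldn19, a claudin of myelinating Schwann cells, 3.10-fold lower (2.95 to 3.26). Cldn1, the main claudin of perineurial cells, was at 196 CPM in WT and 216 CPM in NF1. Of 19 adherens and gap junction genes 7 were lower (median -0.78), among them Pecam1 (3.08-fold, 2.84 to 3.33), Cdh5 (VE-cadherin; 2.28-fold, 2.09 to 2.49) and Cdh1 (E-cadherin; 3.05-fold, 2.76 to 3.38). Of 23 genes of barrier transport and transcytosis 8 were lower and none higher (median -0.61). Plvap, which forms the diaphragms of fenestrated endothelium, was 7.07-fold lower (6.11 to 8.21), Mfsd2a, a lipid transporter that limits transcytosis, 5.37-fold lower (4.46 to 6.50) and the amino acid transporter Slc7a5 3.16-fold lower (2.82 to 3.55). Leukocyte adhesion genes had 5 of 15 lower (median -0.54), including Ackr1 (2.70-fold, 2.33 to 3.14) and P-selectin, Selp (3.15-fold, 2.06 to 4.92). With the length and GC trends removed 5 tight junction (median -0.29), 2 adherens and gap junction (median -0.58), 7 barrier transport (median -0.56) and 5 leukocyte adhesion genes (median -0.50) were at least 2-fold lower. Adipocyte genes were lower in NF1 as well, 21 of 42 with 4 higher (median -0.95).

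The pericyte and smooth muscle list was mixed in NF1, with 2 higher and 3 lower of 16 and a median of -0.41 that was -0.10 once the length and GC trends were removed. Its higher members included desmin, Des, at 1545 CPM in NF1 against 31.5 CPM in WT, a gene that skeletal muscle also expresses, and its lower members included Myh11, a smooth muscle myosin (3.52-fold, 2.97 to 4.20), and Notch3 (2.5-fold, 2.15 to 2.91). Perineurial genes had 2 of 12 lower, Itgb4 and Efnb3 (median -0.57; with the trends removed -0.31, with neither at 2-fold). Nerve fibroblast genes (median -0.09, 1 higher and 1 lower of 18) and lymphatic endothelial genes (median -0.16, 1 lower of 6) stayed within the central 95% of random lists. Collagen and matrix genes had 7 lower of 40 and a median of -0.56, or 3 lower and -0.11 with the trends removed.

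Schwann cell lists other than the myelinating one differed less in NF1. The median was -0.31 for lineage genes, -0.26 for non-myelinating genes and -0.27 for repair and immature genes, each within the central 95% of random lists, and the last was 0.24 without members shared with other lists. The lineage median was -0.41, at percentile 1.1, with the trends removed. Immune lists had medians of 0.02 (macrophage), 0.10 (mast cell; -0.29 with the trends removed), -0.09 (interferon-stimulated), 0.40 (T and NK cell, 2 of 11 higher) and 0.27 (chemokine and cytokine, 6 higher and 1 lower of 33; -0.20 with the trends removed). Single immune genes were apart, with the macrophage fractalkine receptor Cx3cr1 2.26-fold higher (2.05 to 2.51), the scavenger receptor Cd163 2.49-fold lower (2.28 to 2.71), the mast cell tryptase Tpsab1 5.71-fold higher (4.67 to 7.02) and the monocyte chemoattractant Ccl8 6.18-fold higher (4.28 to 9.18). Outside the fixed lists of other tissue, the 12 highest genes included Ankrd23 (77.1-fold, 71.5 to 83.2) and Nmrk2 (at least 256-fold), both expressed in striated muscle. The lowest, after the Y-linked genes, included complement component C7 (25.6-fold lower, 19.7 to 33.9), paraoxonase Pon1 (17.2-fold, 13.5 to 22.3), Rab6b (15.9-fold, 13.3 to 19.3) and Dpysl5 (12.7-fold, 6.4 to 28.5). In total 2458 of 14700 genes met the 2-fold rule, 1531 higher and 927 lower in NF1 (62.3% higher). Scaled by total counts alone, which moved the median of all genes to -0.22, the share was 41.2% higher.

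**Figure D2:**
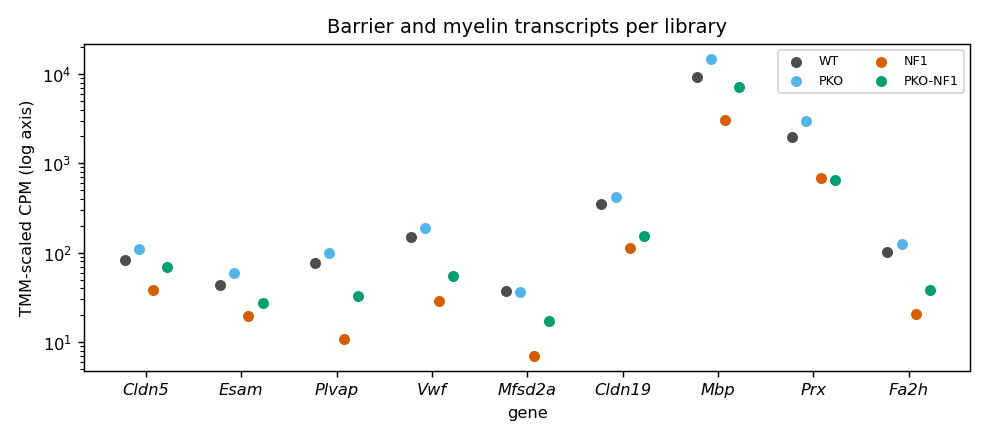
TMM-scaled CPM on a log axis of barrier and myelin genes among those named in the 4 libraries, 1 point per library. The genes shown were picked, after their values had been seen, from named genes that were lower in both NF1 vs WT and PKO-NF1 vs PKO, Cldn5 by less than 2-fold in the latter; Plvap was at 76.4 CPM in WT, 99.0 in PKO, 10.8 in NF1 and 32.8 in PKO-NF1.

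The comparison of PKO-NF1 with PKO asks the same of Nf1 where P2ry14 is absent, in libraries with 0.0838% and 0.0552% of counts from skeletal muscle genes. Endothelial genes were again on the lower side, 9 of 22 by at least 2-fold and none higher (median -0.73), among them Vwf (3.39-fold, 3.15 to 3.65), Robo4 (2.79-fold, 2.36 to 3.31) and Tie1 (2.56-fold, 2.24 to 2.94). Myelinating Schwann cell genes had 7 of 19 lower and 1 higher (median -0.41). Periaxin, Prx, which links the Schwann cell to its basal lamina, was 4.57-fold lower (4.47 to 4.66) and Fa2h, the fatty acid hydroxylase of myelin lipids, 3.21-fold lower (2.94 to 3.51), while Pmp2 was 3.67-fold higher (3.57 to 3.77). Removing the length and GC trends left the endothelial median at -0.54, still at percentile 0 of random lists, with 1 of the 22 genes at least 2-fold lower; the myelinating median became -0.45 with 4 lower.

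Tight junction genes in PKO-NF1 had 7 of 25 lower and 1 higher (median -0.41), including Cldn19 (2.67-fold, 2.55 to 2.80), Cgnl1 (2.15-fold, 2.01 to 2.29) and Esam (2.14-fold, 1.92 to 2.40). That median was -0.13, at percentile 15 of random lists, with the trends removed, and 1 gene was then lower. Barrier transport genes had 5 of 23 lower and 1 higher (median -0.48), led by Plvap (3.02-fold, 2.74 to 3.33) and Slc7a5 (2.55-fold, 2.29 to 2.85), with caveolin Cav2 higher (2.25-fold, 2.17 to 2.34). Adherens and gap junction genes had 4 of 19 lower (median -0.41), among them Cdh5 (2.44-fold, 2.22 to 2.67) and Cdh2 (2.99-fold, 2.52 to 3.57). In barrier transport 2 genes were lower and none higher with the trends removed (median -0.37), and in adherens and gap junctions 1 gene was lower (median -0.36). Adipocyte genes had 10 of 42 lower and 1 higher (median -0.61; 3 lower, 1 higher and a median of -0.49 with the trends removed). Notch3, expressed by pericytes and vascular smooth muscle, was 6.03-fold lower (4.90 to 7.48) and Myh11 3.67-fold lower (3.20 to 4.21). Perineurial genes had 1 higher and 1 lower of 12 (median 0.09, and -0.06 with the trends removed). Skeletal muscle genes had 23 of 69 higher and 5 lower.

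Several Schwann cell and immune lists were on the higher side in PKO-NF1 relative to PKO. The repair and immature and the non-myelinating lists had medians of -0.72 and -1.09 in PKO vs WT, which contains the same PKO library. In PKO-NF1 vs WT their medians were -0.42 and -0.45, or -0.03 and 0.20 with the trends removed. A low level in the PKO library was therefore not separated from a rise with Nf1 loss. The median of repair and immature Schwann cell, PKO-NF1 vs PKO, was 0.41 (0.12 with no expression filter and 1.02 without members shared with other lists), and 4 of 16 genes were higher and none lower, including the corticotropin-releasing family peptide Ucn2 (15-fold, 6.61 to 42.1), the EGF receptor ligand Btc (4.32-fold, 3.09 to 6.15) and the transcription factors Sox2 (2.41-fold, 1.84 to 3.18) and Runx2 (2.65-fold, 1.5 to 4.88). Non-myelinating genes had a median of 0.43 with Chl1 2.40-fold higher (2.20 to 2.62) and Cdh2 lower. Of the 11 lineage genes, Fabp7 was 5.27-fold higher (4.02 to 7.01) and Sox10, the lineage transcription factor, 2.38-fold lower (2.22 to 2.55); the list had 2 higher and 1 lower and a median of 0.19. Cell cycle genes had 5 of 30 higher (median 0.51), such as Ube2c (2.31-fold, 1.61 to 3.36) and Top2a (2.08-fold, 1.49 to 2.91), and 1 of 30 with the trends removed (median 0.38). Macrophage genes had 2 of 30 higher (median 0.35), Cx3cr1 (3.99-fold, 3.47 to 4.60) and Ccr2 (2.59-fold, 2.38 to 2.83). Neutrophil and dendritic cell genes had 5 of 11 higher (median 0.96), including the neutrophil calprotectin gene S100a9 (4.51-fold, 2.92 to 7.21), and 3 with the trends removed (median 0.66). Plasma cell gene Igj was 5.28-fold lower (4.64 to 6.02). Matrix genes were mixed, with Spp1 (osteopontin) 3.01-fold (2.91 to 3.11) and periostin, Postn, 2.10-fold higher (2.03 to 2.18), and Col14a1 2.23-fold lower (2.07 to 2.41). The collagen and matrix list had 4 higher and 7 lower of 40 and a median of -0.44, or 1 higher, none lower and 0.36 with the trends removed. In total 764 genes were higher and 1426 lower (34.9% higher), and removing the trends left 490 and 644 (43.2%). Scaled by total counts the share was 44.8%.

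Both Nf1 pairs, which share no library, had 190 genes higher and 382 lower, where independent lists would share 79.6 and 89.9. Higher in both were epiphycan, Epyc (2.90-fold in NF1 vs WT and 7.87-fold in PKO-NF1 vs PKO), type 2 deiodinase, Dio2 (4.53-fold and 4.06-fold), carbonic anhydrase Car2 (6.16-fold and 3.93-fold), Vamp7 (2.73-fold and 2.90-fold) and the mast cell gene Tpsab1 (5.71-fold and 2.60-fold). Lower in both were the phosphatase Ptprt (5.02-fold and 4.81-fold), Megf6 (6.73-fold and 4.23-fold), the adenylyl cyclase Adcy1 (3.59-fold and 5.62-fold), Vwf and the membrane-type metalloproteinase Mmp15 (3.33-fold and 3.41-fold). With the length and GC trends removed the pairs shared 111 higher and 118 lower genes, against 37.3 and 29.2 for independent lists. GC content moved in parallel with both: genes in the lowest decile of GC had a median of 0.46 in NF1 vs WT and 0.55 in PKO-NF1 vs PKO, and those in the highest decile -0.41 and -0.58.

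An additive edgeR quasi-likelihood model with a term for each genotype gave a test with 1 residual degree of freedom, which is the interaction. At Benjamini-Hochberg adjusted p under 0.05 the Nf1 term called 0 of 14105 genes (2936 at unadjusted p under 0.05; the DESeq2 Wald test called 284). The smallest adjusted p was 0.102, for the muscle genes Ampd1 and Myot, and Ptprt, with a fitted log2 change of -2.30 (SE 0.22), had an adjusted p of 0.169. Adjusted over the list alone, 15 of 22 endothelial genes were lower at the Nf1 term (smallest edgeR adjusted p 0.0077), as were 5 of 19 adherens and gap junction, 3 of 23 barrier transport, 3 of 19 myelinating Schwann cell and 0 of 24 tight junction genes; adjusted over all genes these counts were 0. With the trends removed, 9 endothelial, 2 adherens and gap junction, 3 barrier transport, 2 myelinating Schwann cell and 1 tight junction genes were lower when adjusted over the list alone. At the same term 22 of 55 skeletal muscle genes were higher and 7 of 41 adipocyte genes lower, adjusted over the list alone. With the trends removed 27 muscle genes were higher and 7 adipocyte genes lower. Adjusted over all genes 0 of either list were called, or 5 muscle genes with the trends removed.

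**Figure D3:**
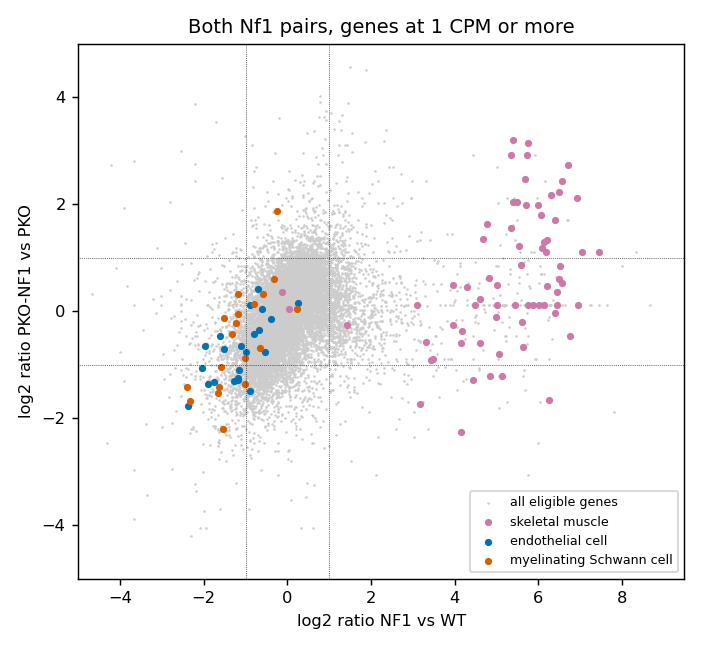
Log2 ratio in NF1 vs WT (horizontal) and in PKO-NF1 vs PKO (vertical) of each gene at 1 CPM or more in at least 1 library, 1 grey point per gene, with 3 lists in colour; dotted lines mark 2-fold and 10 genes lie outside the axes. Endothelial and myelinating Schwann cell genes lie mostly to the lower left, while skeletal muscle genes have a median of 5.61 on the horizontal axis and 0.46 on the vertical axis.

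The comparison of PKO with WT asks what differs when P2ry14 alone is lost. Ribosomal protein genes were higher in PKO, 46 of 47 by at least 2-fold with a median of 5.63-fold (log2 2.49; 41 higher and a median log2 of 1.66 with the length and GC trends removed), among them Rps24 (8.42-fold, 8.25 to 8.60) and Rpl38 (8.22-fold, 7.89 to 8.57). Schwann cell lists other than the myelinating one were on the lower side in PKO. Of 11 lineage genes 4 were lower and none higher (median -0.95), including Lgi4, a secreted factor required for myelination (2.98-fold, 2.86 to 3.10), desert hedgehog, Dhh (2.83-fold, 2.68 to 2.98), and the neuregulin receptor Erbb3 (2.17-fold, 2.02 to 2.34). Non-myelinating genes had 7 of 13 lower and 2 higher (median -1.09), with the potassium channel Kcna1 3.24-fold lower (3.12 to 3.37) and L1cam 3.39-fold lower (3.08 to 3.73). Repair and immature genes had 7 of 16 lower and 1 higher (median -0.72), including Runx2 (6.06-fold, 3.65 to 10.6) and Btc (3.79-fold, 2.70 to 5.42). With the trends removed 5 lineage (median -0.83), 4 non-myelinating (with 2 higher, median -0.65) and 7 repair and immature genes (with 1 higher, median -0.64) were lower.

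Few genes of the barrier lists were 2-fold apart between PKO and WT. No endothelial gene of 22 reached 2-fold (median 0.17, -0.29 when scaled by total counts and 0.17 at percentile 98 with the trends removed). Nor did any of 23 barrier transport genes, and the median of barrier transporter and transcytosis, PKO vs WT, was -0.05, -0.51 when scaled by total counts and 0.20 with the trends removed. Of 25 tight junction genes 1 was higher and 1 lower, and the median of tight junction, PKO vs WT, was -0.10, or -0.56 when scaled by total counts. The median of perineurial cell, PKO vs WT, was -0.26 with Lypd2 higher, -0.72 when scaled by total counts, and -0.30 at percentile 2.2 with the trends removed, where Lypd2 was not 2-fold apart and Crabp2 was lower. Lymphatic endothelial genes had 1 higher and 1 lower of 6 (median 0.57), or 3 higher and none lower with the trends removed (median 0.61, percentile 99.5), and the median of lymphatic endothelial cell, PKO vs WT, was 0.11 when scaled by total counts. Myelinating genes had a median of 0.26 (-0.20 when scaled by total counts); Pmp2 was 2.22-fold lower (2.16 to 2.29). Pericyte and smooth muscle genes had 3 of 16 higher, and the median of pericyte and smooth muscle, PKO vs WT, was 0.47, or 0.0074 when scaled by total counts; the higher genes included the smooth muscle protein transgelin, Tagln (2.21-fold, 2.14 to 2.29), and nerve fibroblast genes 4 of 18 (median 0.66), including dermatopontin, Dpt (2.39-fold, 2.31 to 2.47); with the trends removed 2 and 0 were higher (medians 0.46 and 0.47). Adipocyte genes had 11 of 42 higher, and the median of adipocyte, PKO vs WT, was 0.44, or -0.016 when scaled by total counts; 6 were higher and 2 lower with the trends removed (median 0.38).

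Several immune lists were on the higher side in PKO. Scaled by total counts their medians were smaller, as the median of all genes went from -0.08 to -0.54. Mast cell genes had 6 of 12 higher (median 1.01), among them the chymase Cma1 (3.77-fold, 3.55 to 4.01), Mcpt4 (3.33-fold, 3.16 to 3.51) and the IgE receptor subunit Fcer1a (4.16-fold, 3.42 to 5.10). Chemokine and cytokine genes had 11 of 33 higher (median 0.61), led by Ccl8 (13.1-fold, 9.16 to 19.2), Ccl12 (9.95-fold, 6.13 to 17.2) and Ccl24 (3.60-fold, 3.12 to 4.16). Macrophage genes had 5 higher and 2 lower of 30 (median 0.56), with the signalling adaptor Tyrobp 3.43-fold higher (3.20 to 3.68) and the efferocytosis receptor Mertk 2.51-fold lower (2.28 to 2.77). With the length and GC trends removed these medians were 0.47, 0.23 and 0.16, with 4 mast cell genes higher, 6 chemokine and cytokine genes higher and 4 lower, and 1 macrophage gene higher and 1 lower. T and NK cell genes had 4 of 11 higher (median 0.93), for example Cd3g at 0.472 CPM in WT and 1.69 CPM in PKO, and 2 higher with the trends removed (median 0.44); 4 of the 11 were at 1 CPM or more in all 4 libraries, and the list took 0.0137% of counts in WT and 0.00908% in PKO. Transcripts of neurons, whose cell bodies lie outside the nerve, were higher as well: 5 of 9 were higher and 1 lower (median 1.19), and the sensory neuropeptide Calca was 13.8-fold (9.71 to 20.1), Stmn3 13-fold (11.3 to 15) and peripherin, Prph, 3.68-fold higher (3.0 to 4.53). Skeletal muscle genes had 39 of 70 lower and 2 higher (median -1.74).

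Other genes with the largest differences between PKO and WT were apolipoprotein Apoc1 (7.97-fold higher, 7.26 to 8.77) and the interferon-induced Ifi27l2a (6.01-fold higher, 5.88 to 6.15), and on the lower side Adam11 (17.7-fold, 15.5 to 20.4), the inward rectifier potassium channel Kcnj10 (11.6-fold, 9.08 to 15) and the collagen gene Col27a1 (5.45-fold, 5.0 to 5.96). MAPK feedback target genes had a median of -0.61, with the cyclin Ccnd1 2.13-fold (2.04 to 2.23) and the immediate early gene Egr1 2.11-fold lower (1.90 to 2.35). In NF1 vs WT that list had 0 higher and 2 lower of 19 (median 0.10, or 0.27 at percentile 98.7 with the trends removed). In PKO-NF1 vs PKO it had 2 higher and 1 lower (median 0.20, or 0.12 with the trends removed). Immediate early genes, which respond to dissection, had 1 higher and 2 lower of 25 (median -0.19, or -0.37 at percentile 0.2 with the trends removed). In total 1474 genes were higher and 768 lower (65.7% higher). Scaled by total counts, where the median of all genes was -0.54, 21.6% of calls were higher, and with the trends removed 52.4%. Short transcripts were higher and long ones lower: the shortest decile of genes had a median of 1.02 and the longest -0.49.

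**Figure D4:**
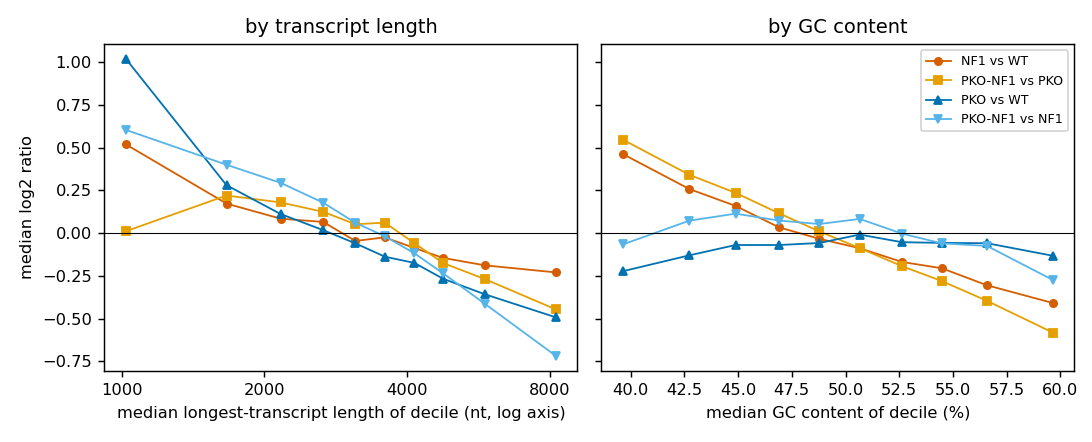
Median log2 ratio of genes in deciles of longest-transcript length (left, log axis, nucleotides) and of GC content (right, percent) for 4 comparisons, 1 point per decile. From the shortest to the longest decile the median went from 1.02 to -0.49 in PKO vs WT and from 0.60 to -0.72 in PKO-NF1 vs NF1.

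The comparison of PKO-NF1 with NF1 asks what differs with P2ry14 loss where Nf1 is also lost. The largest differences were in skeletal muscle genes, 67 of 70 lower in PKO-NF1 (median -6.94), for example Acta1, skeletal muscle actin, at 25.5 CPM against 8972 CPM in NF1. Myelinating Schwann cell genes were higher in PKO-NF1, 8 of 19 and none lower (median 0.93), with Pmp22 3.26-fold (3.21 to 3.30) and Mal 3.05-fold higher (2.97 to 3.14), while Prx was at 656 and 681 CPM. Endothelial genes had 5 of 22 higher, and the median of endothelial cell, PKO-NF1 vs NF1, was 0.48, or 0.79 without members shared with other lists; the higher genes included Ly6c1 (3.09-fold, 2.90 to 3.29), Emcn (3.07-fold, 2.71 to 3.49) and Pecam1 (2.63-fold, 2.43 to 2.85). Adipocyte genes had 19 of 42 higher and 6 lower (median 0.96). Compared with WT, Plvap in PKO-NF1 was still 2.33-fold lower (2.10 to 2.58).

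Barrier transport genes had 6 of 23 higher and 1 lower in PKO-NF1 (median 0.41), among them Plvap (3.04-fold, 2.59 to 3.58), Mfsd2a (2.46-fold, 2.0 to 3.03) and caveolin Cav1 (2.01-fold, 1.96 to 2.06), with the transferrin receptor Tfrc 2.13-fold lower (1.90 to 2.40). Tight junction genes had 4 higher, including the adhesion molecule Jam3 (2.27-fold, 2.13 to 2.42), and 2 lower, including Cgnl1 (2.09-fold, 1.96 to 2.23); the median was 0.23, or -0.05 without members shared with other lists. Adherens and gap junction genes had 3 of 19 higher, where the median of adherens and gap junction, PKO-NF1 vs NF1, was 0.32, or 0.07 without members shared with other lists; leukocyte adhesion genes had 4 of 15 higher (median 0.44), perineurial genes 2 of 12 (median 0.30) and nerve fibroblast genes 5 of 18 (median 0.66). After removal of the trends 2 tight junction and 2 nerve fibroblast genes were higher (medians 0.29 and 0.55). Then 0 tight junction genes were lower, and 1 perineurial gene was higher (median 0.23).

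Macrophage genes had 10 of 30 higher and none lower in PKO-NF1 (median 0.87), led by the antigen presentation genes H2-Aa (4.25-fold, 4.13 to 4.39), H2-Ab1 (2.94-fold, 2.83 to 3.06) and Cd74 (2.46-fold, 2.40 to 2.52). Mast cell genes had 6 of 12 higher (median 0.90), including Fcer1a (4.23-fold, 3.56 to 5.04), and neutrophil and dendritic cell genes 6 higher and 1 lower of 11 (median 1.15), including S100a9 (14.4-fold, 7.32 to 32.4) and Cd209a (4.43-fold, 3.84 to 5.13); with the trends removed 5 macrophage, 2 mast cell and 5 neutrophil and dendritic cell genes were higher (medians 0.57, 0.74 and 0.52). Lineage genes had a median of -0.24 (0.05 with no expression filter) and 3 of 11 lower, or a median of -0.24 at percentile 2.1 and 0 lower with the trends removed. The 3 were Lgi4 (2.32-fold, 2.23 to 2.41), Erbb3 (2.37-fold, 2.14 to 2.63) and Sox10 (2.08-fold, 1.94 to 2.23). Non-myelinating genes had 1 higher and 2 lower of 13 (median -0.36), or 0 and 0 with the trends removed (median 0.18). Repair and immature genes had 3 higher and 4 lower of 16 (median -0.04), or 2 and 3 with the trends removed (median 0.03). Among MAPK feedback targets the inhibitors Spred3 (5.82-fold, 3.85 to 9.15) and Spred2 (2.41-fold, 1.98 to 2.96) were lower. The list had 1 higher and 3 lower of 19 and a median of -0.20, at percentile 18.2 of random lists. Immediate early genes had 6 of 25 higher and 2 lower (median 0.48). Neuron genes had 6 higher and 1 lower of 9 (median 1.28). In total 1162 genes were higher and 2031 lower (36.4% higher; 22.5% when scaled by total counts).

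Both P2ry14 pairs, which share no library, had 436 genes higher and 419 lower, against 117 and 106 for independent lists; with the length and GC trends removed the counts were 168 and 353. Higher in both were Apoc1 (7.97-fold and 9.75-fold), Ifi27l2a (6.01-fold and 9.97-fold), Stmn3 (13-fold and 5.65-fold), Calca (13.8-fold and 5.37-fold) and Fcer1a (4.16-fold and 4.23-fold). Lower in both were muscle genes such as the sodium channel Scn4a and the sarcomere protein Mypn, and also Adam11 (17.7-fold and 5.78-fold). The P2ry14 term of the additive model called 7 genes, all lower and all expressed in skeletal muscle (Ampd1, Mylk4, Myot, Myoz3, Mypn, Scn4a and Xirp2; edgeR adjusted p 0.026), with 3555 genes at unadjusted p under 0.05 and 720 calls by DESeq2. Adjusted over the list alone, 6 of 12 mast cell, 8 of 31 chemokine and 7 of 9 neuron genes were higher, and 32 of 55 skeletal muscle genes were lower; adjusted over all genes, only 3 muscle list members were called. After removal of the trends the list-alone counts were 2 mast cell, 3 chemokine (with 1 lower) and 6 neuron genes higher and 44 skeletal muscle genes lower, with 5 muscle list members called over all genes. P2ry14 itself had a fitted log2 change of -2.21 (SE 0.29) and an adjusted p of 0.141, and Nf1 at the Nf1 term -0.59 (SE 0.27) with 0.285.

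**Figure D5:**
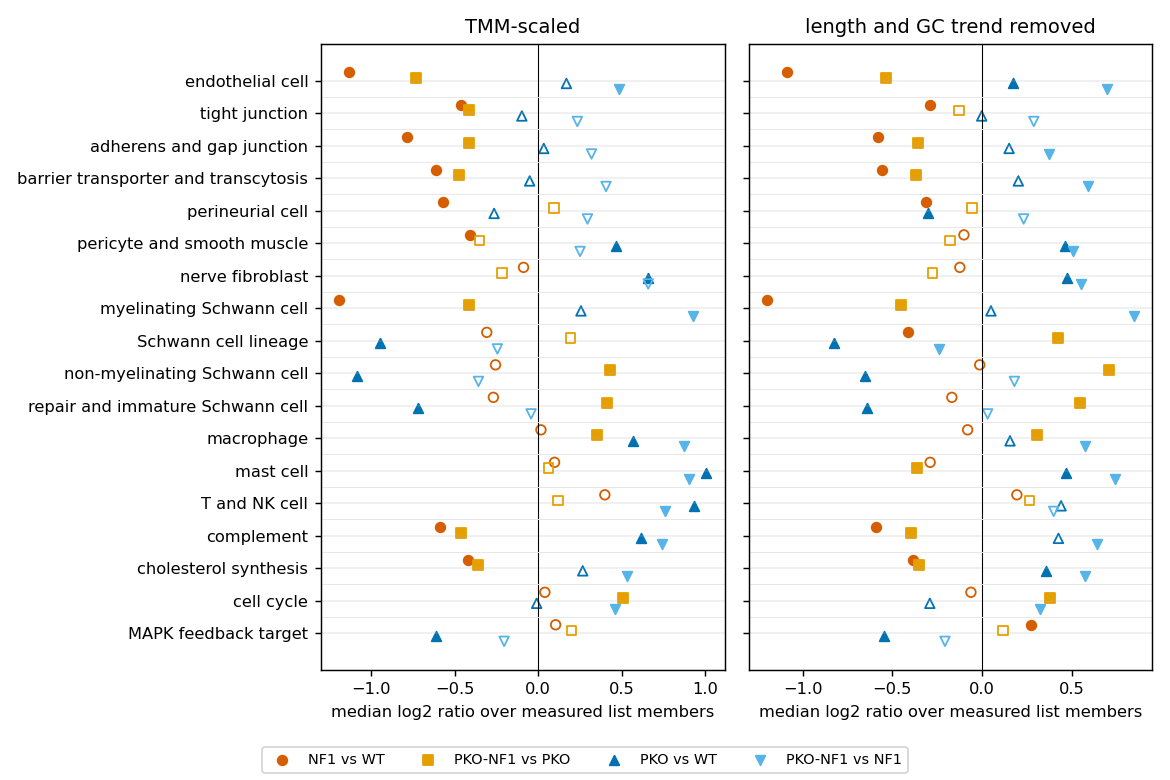
Median log2 ratio over the measured members of gene lists in 4 comparisons, with TMM scaling (left) and after removal of the length and GC trends (right). Filled marks lie outside the central 95% of 10000 random lists matched on expression; the endothelial medians in NF1 vs WT were -1.13 and -1.09.

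Of the 1531 genes higher in NF1 than in WT, 671 (43.8%) were at least 2-fold lower in PKO-NF1 than in NF1, and of the 927 lower genes 253 (27.3%) were at least 2-fold higher. Both comparisons contain the NF1 library, so a difference confined to that library would also make genes return. The simulations given next hold no such difference, so they do not separate it from P2ry14 loss. In simulated libraries without a P2ry14 effect 9.48% of the higher and 13.1% of the lower genes returned (medians of 100 simulations), which were 174 (147 to 202) and 214 genes (179 to 243) of simulated sets that differ in size from 1531 and 927. In PKO-NF1 vs PKO, which shares no library with the choice of these genes, the 1531 had a median of 0.12 with 190 at least 2-fold higher, and the 927 had a median of -0.85 with 382 at least 2-fold lower. Without the lists of other tissue, 41.2% of the higher and 26.4% of the lower genes returned. With the length and GC trends removed 712 of 1119 higher genes (63.6%) and 290 of 667 lower genes (43.5%) returned; in PKO-NF1 vs PKO these 1119 had a median of 0.07 with 111 at least 2-fold higher, and the 667 a median of -0.41 with 118 at least 2-fold lower. PKO-NF1 differed from WT at 4726 genes, 2154 higher and 2572 lower (45.6% higher; 19.7% when scaled by total counts), and at 1840 with the length and GC trends removed, 921 higher and 919 lower.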

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

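The tests used to weigh explanations in this part were chosen after the results they address had been seen, and the muscle test in PKO-NF1 vs PKO replaced a first version computed against WT. The bound that would have excluded a ribosomal protein change was also altered after its value had been seen. The differences between backgrounds given next have 1 library per genotype and were not tested. In the Nf1 pairs, 84 genes were at least 2-fold apart in opposite directions, where independent lists would give 197, and in the P2ry14 pairs 61 genes were, against 264. The erythroid list was lower in NF1 than in WT and higher in PKO-NF1 than in PKO, a difference of medians of -4.46, although the median of erythroid, NF1 vs WT, was -0.72 and the median of erythroid, PKO-NF1 vs PKO, 1.59 with a 5 CPM filter; the heme synthesis gene Alas2 was at 14.9 CPM in WT, 10.9 in PKO, 126 in PKO-NF1 and 4.57 in NF1. The ribosomal protein list was higher in NF1 than in WT and lower in PKO-NF1 than in PKO, a difference of medians of 1.60.

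The first pattern is the 48.7-fold median excess of skeletal muscle genes in NF1 over WT. An effect of Nf1 loss whatever the P2ry14 genotype is argued against by the median of 0.46 in PKO-NF1 vs PKO, set against 5.61 in NF1 vs WT. Muscle carried into the NF1 library with the nerve remains a candidate source, and Acta1 reached 8972 CPM and Mylpf 8362 CPM in NF1. Across 70 muscle genes the CPM of NF1 and WT had a Spearman rho of 0.93. Across all genes rho was 0.917, so this rank correlation cannot decide. Of the 70 genes 36 were at 1 CPM or more in every library and 1 is in another list. An effect of Nf1 loss that needs intact P2ry14 cannot be told apart from carried muscle. The median of -6.94 in PKO-NF1 vs NF1 would follow from either with 1 library per genotype.

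The second pattern is that short transcripts were higher and long ones lower in both P2ry14-null libraries, together with a 5.63-fold median excess of ribosomal protein genes in PKO over WT. Without ribosomal and respiratory chain genes the gap between the shortest and longest decile was still 1.37 in PKO vs WT and 1.33 in PKO-NF1 vs NF1, which is consistent with RNA or library handling that differs with transcript length; it was 0.62 in NF1 vs WT and 0.52 in PKO-NF1 vs PKO. Higher ribosomal protein transcripts after P2ry14 loss in both backgrounds stay open. With the trends removed the list median was 1.66 at percentile 100 in PKO vs WT and 0.38 at percentile 49.5 in PKO-NF1 vs NF1. At the P2ry14 term 47 of 47 members were fitted higher, but none was called over the list alone (smallest edgeR adjusted p 0.109). At the Nf1 term 45 of 47 were also fitted higher, or 28 with the trends removed. A ribosomal protein change after P2ry14 loss cannot be told apart from handling. Removing a length trend also removes a change shared by short transcripts, and each genotype is 1 library.

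The third pattern is the lower level of endothelial and myelinating Schwann cell genes in both libraries labelled with the Nf1 mutation. At gene level Nf1 itself was higher in NF1 than in PKO, whose genotype leaves it intact. Dilution by muscle RNA as the source in both pairs is argued against by the endothelial median of -0.73 in PKO-NF1 vs PKO. Muscle genes took 0.0838% of counts in PKO-NF1 and 0.0552% in PKO. The myelinating median was -0.41 in that pair, against -1.19 in NF1 vs WT. How far muscle RNA, with 8.80% of counts in NF1, added to the medians of NF1 vs WT was not tested. A length and GC trend as the whole cause is argued against by the highest of the 4 percentiles with the trends removed, 0.2, although the number of endothelial genes 2-fold lower in PKO-NF1 vs PKO went from 9 to 1 as the median went from -0.73 to -0.54, and the sex of the animals by Xist, whose log2 ratio was -8.98 in PKO-NF1 vs PKO and 1.73 in NF1 vs WT while both lists went the same way. Nf1 loss in Dhh-Cre cells may account for the pattern, but no value here tests it separately. At the edgeR Nf1 term 15 of 22 endothelial genes were lower adjusted over the list alone, and 0 adjusted over all genes. That count uses the same libraries as the pattern, so it restates that both pairs went the same way. Of all 14105 genes 2936 were at unadjusted p under 0.05 at this edgeR term. Nf1 itself was 1.15-fold lower in NF1 vs WT, where the endothelial median was -1.13. In PKO-NF1 vs PKO Nf1 was 2.0-fold lower, and the endothelial median was -0.73. Nf1 loss cannot be told apart from other differences between single libraries, such as the amount of vessel or fat in each sample, for which no test was run. The adipocyte medians (42 genes, 40 of them at 1 CPM or more in all 4 libraries and 1 in another list) were -0.95 in NF1 vs WT and -0.61 in PKO-NF1 vs PKO. At the Nf1 term, adjusted over the list alone, 7 of 41 adipocyte genes were lower and 22 of 55 skeletal muscle genes higher.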

How the results depend on the processing

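The length and GC trend removal and the third split of the libraries were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each genotype has 1 library, so the shared replicate number pairs nothing. DESeq2 size factors, no filter, a 5 CPM filter and removal of other-tissue lists left each count of 2-fold genes within 1.5 times of its value. Single genes were followed for Nf1, P2ry14 and the genes ranked highest or lowest in a pairwise comparison or over both pairs. Genes named only as list members or from the additive model were not followed. Among those followed, none that met the 2-fold rule changed sign under the scaling, filter or trend alternatives, but sizes did change. Of their ratios, 84 were classed as moved and 96 as the same with the trends removed. Under total counts 41 were classed as moved and 141 as the same. A 1.5-fold threshold, which by construction admits more genes, gave 5266 genes in NF1 vs WT, 5250 in PKO-NF1 vs PKO, 4630 in PKO vs WT, 6475 in PKO-NF1 vs NF1, 8006 in PKO-NF1 vs WT, 2138 in both Nf1 pairs, 2668 in both P2ry14 pairs and 1725 returning genes. The cause of the following was not tested. Total counts gave 3477 genes in PKO vs WT and 1459 in both P2ry14 pairs. With the trends removed there were 1134 genes in PKO-NF1 vs PKO, 1840 in PKO-NF1 vs WT, 229 in both Nf1 pairs and 521 in both P2ry14 pairs. The median of all genes under total counts was -0.22 in NF1 vs WT, 0.08 in PKO-NF1 vs PKO, -0.54 in PKO vs WT, -0.18 in PKO-NF1 vs NF1 and -0.37 in PKO-NF1 vs WT.

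The additive Nf1 term, with 0 edgeR calls, had 284 by the DESeq2 Wald test, 47 with no filter, 12 with the trends removed, and 0 to 81 when each library was left out of a model with 1 term, the 81 without PKO-NF1; the lone library is then assumed to vary like the others. The P2ry14 term, with 7 calls, had 720 by DESeq2, 106 with no filter, 17 with the trends removed, 4 without other-tissue lists, 0 with 1 term, and 0 to 350 when each library was left out, 350 without WT and 31 without NF1. With 1 term the Nf1 split had 1136, the P2ry14 split 1806 and the third way of splitting the libraries into pairs 201 genes at unadjusted p under 0.05, each with 0 calls.

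Of 152 list medians, 152 moved by less than the SD of their matched random lists under DESeq2 size factors; 70 moved further and 2 reversed under total counts, 47 and 4 with the trends removed, and 6 and 1 with no filter, while 12 moved further without shared members. With a 5 CPM filter, which left too few members of some lists, 10 moved further and 134 did not. With the trends removed collagen and matrix reversed to 0.36 in PKO-NF1 vs PKO and 0.32 in PKO vs WT, and the semaphorin list to 0.0046 in PKO vs WT and 0.069 in PKO-NF1 vs NF1. Under total counts the median of angiogenic factor, PKO vs WT, reversed to -0.30 and the median of adipocyte, PKO vs WT, to -0.016. With no filter the median of B and plasma cell, PKO-NF1 vs PKO, reversed to 0.25. The cause was not tested. The log2 ratio of Nf1, NF1 vs WT, was -0.41 under total counts and -0.024 with the trends removed, and in PKO-NF1 vs PKO -0.58 with the trends removed. The log2 ratio of P2ry14, PKO vs WT, was -2.25 under total counts, -1.33 with the trends removed, and -2.14 in PKO-NF1 vs NF1 with the trends removed. Depth limits genes near 3 counts, 0.152 to 0.183 CPM.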

Other observations

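The values in this part come from lists and gene rules fixed beforehand, apart from the removal of length and GC trends, and no test of an explanation was run for them. Of 30 semaphorin, plexin and ephrin genes, which guide axons and vessels, 8 were lower and 1 higher in NF1 vs WT (median -0.76) and 11 lower in PKO-NF1 vs PKO (median -0.64), and with the trends removed 4 were lower and 1 higher and 3 were lower (medians -0.24 and -0.19). The edgeR Nf1 term called 11 of 30 lower adjusted over the list alone and 0 adjusted over all genes (2936 of all genes were at unadjusted p under 0.05); with the trends removed it called 0 adjusted over the list alone, and 17 of the 30 were fitted lower and 13 higher. Sema5a was 3.93-fold (3.66 to 4.21) and 2.90-fold lower (2.70 to 3.12), and Sema3g 3.17-fold (2.89 to 3.48) and 2.90-fold lower (2.60 to 3.24). Angiogenic factor genes had 5 and 4 of 32 lower and 1 higher in NF1 (medians -0.42 and -0.35), among them the VEGF receptors Flt1 (2.28-fold and 2.38-fold) and Flt4 (3.13-fold and 3.84-fold). Cholesterol synthesis genes had 3 and 5 of 19 lower and 1 higher in PKO-NF1 (medians -0.42 and -0.36; 3 and 2 lower, none higher and medians of -0.39 and -0.35 with the trends removed), and their median was 0.53 in PKO-NF1 vs NF1. Complement genes had 3 and 2 of 15 lower (medians -0.59 and -0.46), with C4b 2.36-fold and 2.01-fold lower, and 2 of 15 were higher in PKO vs WT (median 0.62), C3 by 2.35-fold (2.29 to 2.42) and adipsin, Cfd, by 2.71-fold (2.68 to 2.74); with the trends removed 4 complement genes were lower in NF1 vs WT (median -0.59), 0 in PKO-NF1 vs PKO (median -0.40, percentile 0.6), and 1 was higher in PKO vs WT (median 0.43).

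Among genes of cAMP signalling, the adenylyl cyclases Adcy1 and Adcy6 were lower in both Nf1 pairs, by 3.59-fold and 5.62-fold and by 2.23-fold and 2.44-fold, while phosphodiesterases Pde4d (4.12-fold, 3.59 to 4.73) and Pde7a (3.59-fold, 3.26 to 3.96) were higher in NF1 than in WT and 6.47-fold and 5.61-fold lower in PKO-NF1 than in NF1, libraries in which skeletal muscle genes took 8.80% (NF1), 0.220% (WT) and 0.0838% (PKO-NF1) of counts. The list had 6 higher and 5 lower of 34 in NF1 vs WT (median -0.36) and 10 lower in PKO-NF1 vs PKO (median -0.35); with the trends removed the medians were -0.09, at percentile 19.1, and -0.31 with 2 lower. The purinergic list, which covers the family of P2ry14, had 4 of 23 higher and 1 lower in NF1 vs WT (median 0.10) and 4 higher in PKO-NF1 vs PKO (median 0.17), including the ectonucleotidase Nt5e, also known as CD73 (3.25-fold, 2.99 to 3.54). P2ry12 was 2.27-fold lower in PKO than in WT (1.73 to 3.0). It was 3.35-fold higher in PKO-NF1 than in PKO (2.59 to 4.37), a comparison that contains the same PKO library. With the trends removed the purinergic list had 3 higher and 1 lower in NF1 vs WT and 1 higher in PKO-NF1 vs PKO (medians -0.09 and -0.01).

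Adipocyte genes had 21 of 42 lower and 4 higher in NF1 vs WT (median -0.95), 10 lower and 1 higher in PKO-NF1 vs PKO (median -0.61), 11 higher in PKO vs WT (median 0.44, but with the median of adipocyte, PKO vs WT, at -0.016 under total counts) and 19 higher and 6 lower in PKO-NF1 vs NF1 (median 0.96). Leptin, Lep, was at 140 CPM in WT, 110 in PKO, 152 in PKO-NF1 and 9.84 in NF1. Hypoxia and glycolysis genes had 6 of 19 higher in NF1 vs WT, and the median of hypoxia and glycolysis, NF1 vs WT, was 0.65, or 0.31 without members shared with other lists; the higher genes included Aldoa (9.07-fold, 8.88 to 9.27) and Ldha (4.05-fold, 3.92 to 4.19), which skeletal muscle also expresses. Immediate early genes, which respond to dissection, had 6 of 25 lower in NF1 vs WT (median -0.47; 1 lower and -0.39 with the trends removed), and Fos was at 25 CPM in WT, 6.52 in PKO, 16.8 in PKO-NF1 and 19.5 in NF1. Of 5 keratinocyte genes 2 were higher in PKO vs WT, or 0 with the trends removed, and the median of keratinocyte, PKO vs WT, was 1.00, or 0.65 with the trends removed, 0.54 under total counts and 0.36 with no expression filter, with Krtdap at 3.89 and 14.3 CPM. B and plasma cell genes had 3 of 5 higher in PKO vs WT, or 2 with the trends removed, and the median of B and plasma cell, PKO vs WT, was 1.33, or 0.97 with the trends removed and 0.53 with no expression filter, with Igj at 14 CPM in WT and 89.2 CPM in PKO.

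H2-Ea-ps, an E alpha class II gene that C57BL/6 mice do not normally transcribe, had no counts in WT and NF1 and was at 1.52 CPM in PKO and 7.38 CPM in PKO-NF1, at least 8.58-fold higher in PKO vs WT and at least 48.5-fold higher in PKO-NF1 vs NF1. The 4 libraries are labelled C57BL/6, and the breeding of the P2ry14-null line is not given in the sources used here. A difference of strain background in the P2ry14-null libraries was therefore not separated from loss of P2ry14, for this gene or for other genes of the region such as H2-Aa and H2-Ab1.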
